A study of Acinetobacter calcoaceticus with 9 samples.

How the data were processed

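RNA was measured by sequencing in 9 libraries of Acinetobacter calcoaceticus Aca13, with 3 control libraries, 3 with hexadecane and 3 with naphthalene. Cells were grown in LB medium to logarithmic phase, hexadecane or naphthalene was added, and RNA was taken after 3 h of induction, per the labels' protocols. These give no dose of either compound and no time for the controls, so that a difference in time between control and treated libraries is not excluded. Libraries were depleted of ribosomal RNA and made with a strand-specific kit (NEBNext Ultra Directional), per the labels' protocols. The labels number the libraries of each group 1 to 3 and do not state that these were separate cultures, so p-values measure only the spread between these samples.

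The authors deposited raw read counts per gene, with HTSeq 0.6.1 named for counting per the submitters' processing notes. The aligner and the genome build were not given in the sources used here, apart from the name of 1 reference sequence per the file headers and cells, and no genome was used here. The deposited FPKM values equalled count divided by gene length and by 1 constant per library, as computed from the deposited table. The log2 fold changes, p-values and adjusted p-values that the authors deposited come from DESeq, with no version or settings, per the submitters' processing notes. Gene symbols, product descriptions and coordinates are those of the authors' deposited table, and no other annotation was used.

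The authors' deposited table held 4175 features, of which 3747 were annotated genes and 428 were unannotated regions whose making is not described. A symbol was given for 887 features, 30 symbols were shared by more than 1 gene, and 508 annotated products were hypothetical proteins. Another feature on the same strand overlapped 575 features, and how reads in such overlaps were assigned is not stated. Genes are named by symbol where there is one and by locus tag otherwise.

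Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Weakly expressed features were removed with filterByExpr (minimum count 10, minimum total count 15), which left 3741 features, 3413 annotated and 328 unannotated, and removed 434. Library sizes were scaled by the trimmed mean of M-values (TMM), and CPM values are on that scale. A robust quasi-likelihood model was fitted to all 9 libraries with 1 mean per group and 6 residual degrees of freedom. The common biological coefficient of variation was 0.141 and the median prior degrees of freedom 7.55. The contrasts were hexadecane against control, naphthalene against control and hexadecane against naphthalene, and p-values were adjusted by the Benjamini-Hochberg method within each. A gene was called at an adjusted p under 0.05. Groups, contrasts, gene lists and the rule for named genes were chosen before the data were examined.

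Library totals ran from 3135151 to 4019378 counts, so that 3 counts corresponded to 0.746 to 0.957 CPM. These floors cover counting error only. Tested on simulated counts for 3741 genes, the procedure recovered 55.2%, 82.1% and 95.5% of genes changed by 1.5-fold, 2-fold and 4-fold for hexadecane against control. The shares were 47.8%, 73.1% and 98.5% for naphthalene against control and 53.7%, 79.1% and 92.4% for hexadecane against naphthalene. Unchanged genes made up 8.28%, 6.41% and 5.66% of the simulated calls in the same order of contrasts. The simulated counts had the same spread per gene in all groups, although controls correlated less within their group than treated libraries. These shares may therefore be too favourable for the contrasts against control.

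Genes named in the text followed a fixed rule. For each treatment against control these were the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 10 CPM in 1 of the groups, no overlap between groups, and an informative symbol or product. For hexadecane against naphthalene the number was 5 in each direction. Up to 4 members with the smallest p of each gene list discussed and a fixed set of alkane, aromatic, glyoxylate, efflux and stress genes were added where measured. A gene named outside this rule is described as chosen after its values were seen.

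There were 28 gene lists, drawn up from symbols and product descriptions, and 23 of them had at least 5 tested members. These covered alkane hydroxylation, alcohol and aldehyde dehydrogenases, fatty acid beta-oxidation, fatty acid synthesis, the glyoxylate shunt, the TCA cycle, wax ester storage, aromatic compound degradation and phenylacetate degradation. They also covered multidrug efflux, outer membrane asymmetry, envelope assembly, capsule, type IV pili, type VI secretion, chaperones and proteases, oxidative stress defence, osmoprotection, and SOS response. The remaining lists were iron uptake, iron-sulfur cluster assembly, sulfur acquisition, amino acid catabolism, ATP synthase, NADH dehydrogenase I, terminal oxidases, ribosomal proteins and prophage genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move, on balance, in 1 direction and makes no comparison with other genes.

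The alternatives were other size factors (RLE, upper quartile, total counts), no low-count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, and limma on deposited FPKM with pseudocounts of 1 and 0.1. Further alternatives were a fit of only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. For the lists, membership by symbol only was also tried. Single genes were not followed in the fits on FPKM. Leaving out the unannotated regions and defining ATP synthase by product name were chosen after seeing the data. Splits of the 6 libraries of each contrast into other groups of 3 were counted. No sample column of the deposited table was left out.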

Results

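Transcripts of Acinetobacter calcoaceticus Aca13 were counted in 9 libraries, with 3 untreated controls, 3 libraries with hexadecane and 3 with naphthalene. Treated cells were taken after 3 h of induction, and the labels state no time for the controls. Totals were 3627427, 3476450 and 3292492 counts for control libraries 1 to 3, 4019378, 3432783 and 3885318 with hexadecane, and 3373267, 3329492 and 3135151 with naphthalene. Group means were 3465456 ± 167738, 3779160 ± 307369 and 3279303 ± 126744 counts (SD, n = 3). Correlations of log2 CPM within groups were 0.969 to 0.982 for controls, 0.99 for hexadecane and 0.987 to 0.989 for naphthalene. Control library 1 correlated at 0.969 and 0.975 with the other controls, which correlated at 0.982 with each other. Control library 2 correlated more closely with hexadecane libraries 1 to 3 (0.988, 0.987 and 0.987) than with either other control. Control library 3 correlated at 0.981, 0.981 and 0.983 with them, so by correlation the controls did not group apart from hexadecane. The main axis of variation (38.3%) separated naphthalene (18.9 to 20.6) from all other libraries (-13.9 to -7.57), and the next axis (22.5%) set apart control library 1 (24.8). Levels below are mean CPM ± SD (n = 3) and fold changes are edgeR estimates.

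Hexadecane against control asked which transcripts responded to a long-chain n-alkane. The largest rise among the named genes was that of LRO55_RS12655, annotated as an alkane 1-monooxygenase, the type of enzyme that hydroxylates the end carbon of an n-alkane. Its level was 300.5 ± 55.8 CPM with hexadecane against 7.08 ± 2.93 CPM in controls, a 41.9-fold rise (log2 fold change 5.39, SE 0.23, adjusted p = 1.19e-08), and it was 10.9 ± 0.454 CPM with naphthalene. The gene lies at 2668546 to 2669739 on the minus strand of the reference sequence in the authors' deposited table. LRO55_RS11205, a stress-induced protein at 2366158 to 2366943, rose 2.07-fold from an already high level, from 4901 ± 513 to 10160 ± 1243 CPM (adjusted p = 0.000297). LRO55_RS09975, the other annotated alkane 1-monooxygenase, had a log2 fold change of 0.02 (adjusted p = 0.976).

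The remaining named rises with hexadecane were smaller. An oligosaccharide repeat unit polymerase (LRO55_RS18335) rose 1.77-fold (adjusted p = 0.0289), a TetR/AcrR family regulator (LRO55_RS10615) 1.68-fold (0.0282), and modA, a molybdate-binding transport protein, 1.63-fold (0.0145). A HAD-IA family hydrolase (LRO55_RS15085) rose 1.52-fold (0.046), a glutamine amidotransferase domain protein (LRO55_RS08335) 1.48-fold (0.0234), and an ArsR family regulator (LRO55_RS00845) 1.47-fold (0.0246). A flavodoxin family protein (LRO55_RS03830) rose 1.40-fold (0.0282) and an iron-containing redox enzyme (LRO55_RS11230) 1.39-fold (0.022). The named falls were in aroD, catA, a siderophore gene and a putative hydro-lyase. Expression of aroD, a 3-dehydroquinate dehydratase, went from 13.2 ± 1.20 to 6.18 ± 1.11 CPM, 2.14-fold lower (adjusted p = 0.0379). Expression of catA, the catechol 1,2-dioxygenase that opens the aromatic ring, went from 26.7 ± 3.39 to 12.57 ± 1.999 CPM, 2.12-fold lower (0.0246). The IucA/IucC family siderophore gene LRO55_RS07360 fell by a log2 fold change of 0.88 (0.0359) and the hydro-lyase LRO55_RS11855 by 0.64 (0.0208). LRO55_RS18335 and modA each overlap a neighbour on the same strand by 4 bp, so a few reads may belong to the neighbour.

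Genes that act with the alkane 1-monooxygenase or on its products were followed by name and did not pass the threshold with hexadecane. Log2 fold changes were -0.19 for the rubredoxin LRO55_RS13625 (adjusted p = 0.608), -0.09 for fadB (0.698), -0.15 for isocitrate lyase LRO55_RS13560 (0.512), 0.01 for malate synthase G LRO55_RS10165 (0.963), and -0.08 for the wax ester synthase LRO55_RS03525 (0.804). In the beta-oxidation list an acyl-CoA dehydrogenase (LRO55_RS12440) rose by 0.48 (0.0216), and in the list of alcohol and aldehyde dehydrogenases LRO55_RS18060, a methylmalonate-semialdehyde dehydrogenase of valine breakdown, rose by 0.43 (0.0305). These calls were lost without hexadecane library 1, 2 or 3 (0.0568, 0.191 and 0.127 for LRO55_RS12440, 0.128, 0.247 and 0.127 for LRO55_RS18060) or naphthalene library 1 (0.0529 and 0.0847), and that of LRO55_RS18060 also without naphthalene library 2 (0.0508) or 3 (0.084). They were lost as well with upper-quartile factors (0.0806 and 0.102), total counts (0.095 and 0.129) and only the 6 libraries compared (0.124 and 0.178). The alkane hydroxylation list had 4 tested members, of which only LRO55_RS12655 was called. Beta-oxidation had 1 of 45 members higher (camera adjusted p = 0.751) and alcohol and aldehyde dehydrogenases 1 of 25 (0.72). Of the other genes followed throughout, benA (-0.98, adjusted p = 0.112), pcaH (-0.63, 0.0767), salA (-0.44, 0.583), adeJ (-0.33, 0.189), groL (0.19, 0.538), katG (-0.07, 0.793) and katE (0.23, 0.468) were not called. Without control library 2 benA (0.00738), pcaH (0.0148) and adeJ (0.0209) passed, and without control library 1 pcaH (0.0453) and katE (0.00278).

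Aromatic compound degradation was shifted down with hexadecane as a list. Of 32 members only catA fell over all genes tested, 9 fell adjusted over the list alone, and the median log2 fold change was -0.43 (camera adjusted p = 3.57e-06; adjusted p = 0.528 with an estimated correlation). Members with the smallest p also included pcaB (-0.72, adjusted p = 0.0683), the ferredoxin reductase LRO55_RS12610 (-1.18, 0.0678) and pcaH. Over all genes DESeq2 called 6 members, among them pcaB (0.0118), LRO55_RS12610 (0.0149), pcaH (0.0197) and benA (0.0224), limma-voom called 1, and 4 were lower with total counts. Without control library 1 or 2 pcaB passed (0.00165 and 0.0417), as did LRO55_RS12610 without control library 2 (0.0224). In all, 4, 8 and 1 members were lower without control library 1, 2 or 3, and 0 without hexadecane library 1, 2 or 3. Iron uptake had 1 of 38 members lower, LRO55_RS07360, and 3 adjusted over the list alone, with a median of -0.36 (1.82e-06; adjusted p = 0.528 with an estimated correlation). Among its other members were LRO55_RS07365 (-0.70, 0.0709) and LRO55_RS09885 (-1.55, 0.0792). DESeq2 called 4 iron uptake members and limma-voom 1, and 0 were lower with upper-quartile factors and 2 with total counts. LRO55_RS07365 passed without control library 1 or 3 (0.0379 and 0.031) and LRO55_RS09885 without control library 1, 2 or 3 (0.0132, 0.0448 and 0.02). In all, 3, 3 and 6 members were lower without these libraries, and 0 without hexadecane library 1, 2 or 3. Multidrug efflux had a median of -0.19 over 46 members, with 2 lower adjusted over the list alone, among them LRO55_RS07355 (-0.73, adjusted p = 0.0834 over all genes) and LRO55_RS06145 (-1.24, 0.0958). Its camera adjusted p was 0.000958 (adjusted p = 0.528 with an estimated correlation), and the call was lost without control library 1 (0.204) and with membership by gene symbols only (0.202). In edgeR 0 efflux members passed over all genes, with 14 at an unadjusted p under 0.05, 1 by DESeq2, LRO55_RS07355 (0.03), and 0 by limma-voom. Without control library 2, 5 efflux members were lower, among them LRO55_RS07355 (0.0491), LRO55_RS06145 (0.0263), adeI (0.049) and adeJ. Genes of weak expression were generally lower with hexadecane. Medians were -0.29 in the lowest 20% by expression and -0.0994 in the next 20%. Control library 1 was itself above the other controls in the lowest 20% (median log2 difference 0.203). Features with 0 counts numbered 79, 109 and 81 in control libraries 1 to 3, against 113 to 120 with hexadecane. Differences between control libraries may thus add to this trend, which was not tested. For 10000 random lists matched on expression, the central 95% of medians ran from -0.105 to 0.0844 (iron uptake) and -0.104 to 0.0709 (efflux). This comparison was chosen after these values were seen. Both lists lay below these ranges. Random lists ignore that members vary together (estimated correlation 0.141 for iron uptake and 0.188 for efflux). The ranges are therefore too narrow, and whether the lists depart from the trend of weakly expressed genes is left open.

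Phenylacetate degradation was also lower as a list of 11 members (median -0.29, camera adjusted p = 0.0258; adjusted p = 0.699 with an estimated correlation), a call lost without control library 3 (0.594), hexadecane library 1 (0.071) or hexadecane library 3 (0.0816). Camera called chaperones and proteases higher as a list, with a median of 0.14 and 0 of 14 members called (camera adjusted p = 0.0159). With an estimated correlation its adjusted p was 0.528. The smallest p in the list was that of dnaJ, at 0.36 (adjusted p = 0.28), and the list's call was lost without control library 1 (0.0511). Envelope assembly had a median of 0.17 over 15 members (0.0159; adjusted p = 0.528 with an estimated correlation), with carO at 0.62 (0.18), and its call was lost without control library 3 (0.277). With upper-quartile factors and total counts the medians were smaller, 0.0443 and 0.0212 for chaperones and 0.0817 and 0.0574 for envelope assembly. DESeq2 called carO (0.0443), and without control library 1 or 2 its adjusted p was 0.00967 and 0.0173. Oxidative stress defence had 4 members higher and 1 lower adjusted over the list alone, among them LRO55_RS10765 (0.46, 0.0683) and msrB (0.50, 0.113), and a camera adjusted p of 0.0436 over 19 members (adjusted p = 0.528 with an estimated correlation). Its median of 0.0885 ran from -0.03 to 0.0949 and so turned sign with the scaling. That call was lost without control library 2 (0.0742), control library 3 (0.201), hexadecane library 2 (0.0731) or hexadecane library 3 (0.0816). It was also lost with membership by gene symbols only (0.408) and with the replicate number as a block (0.0612). LRO55_RS10765 passed by DESeq2 (0.0224) and without control library 1 or 2 (0.0255 and 0.0286). In edgeR 0 members of phenylacetate degradation, chaperones, envelope assembly and oxidative stress defence passed over all genes, with 3, 1, 5 and 7 at an unadjusted p under 0.05, 0, 0, 1 and 1 by DESeq2, and 0 in each by limma-voom. Without control library 1 or 2 carO of envelope assembly passed, as did 5 and 1 members of oxidative stress defence, and without control library 2 paaZ of phenylacetate degradation (0.049). Against random lists matched on expression the median lay below the range for phenylacetate degradation (-0.117 to 0.173) and above it for envelope assembly (-0.0567 to 0.17). It lay within the range for chaperones (-0.0702 to 0.17) and oxidative stress defence (-0.0487 to 0.161). These ranges are too narrow for members that vary together (estimated correlation 0.74 for phenylacetate degradation and 0.144 for envelope assembly). The other lists had camera adjusted p from 0.0503 to 0.831, and fry called 0 lists at an adjusted p under 0.05. For alcohol and aldehyde dehydrogenases the median was 0.00524, the mean -0.068 and the test down, and for type IV pili the median was -0.0826, the mean 0.0743 and the test up.

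**Figure D1:**
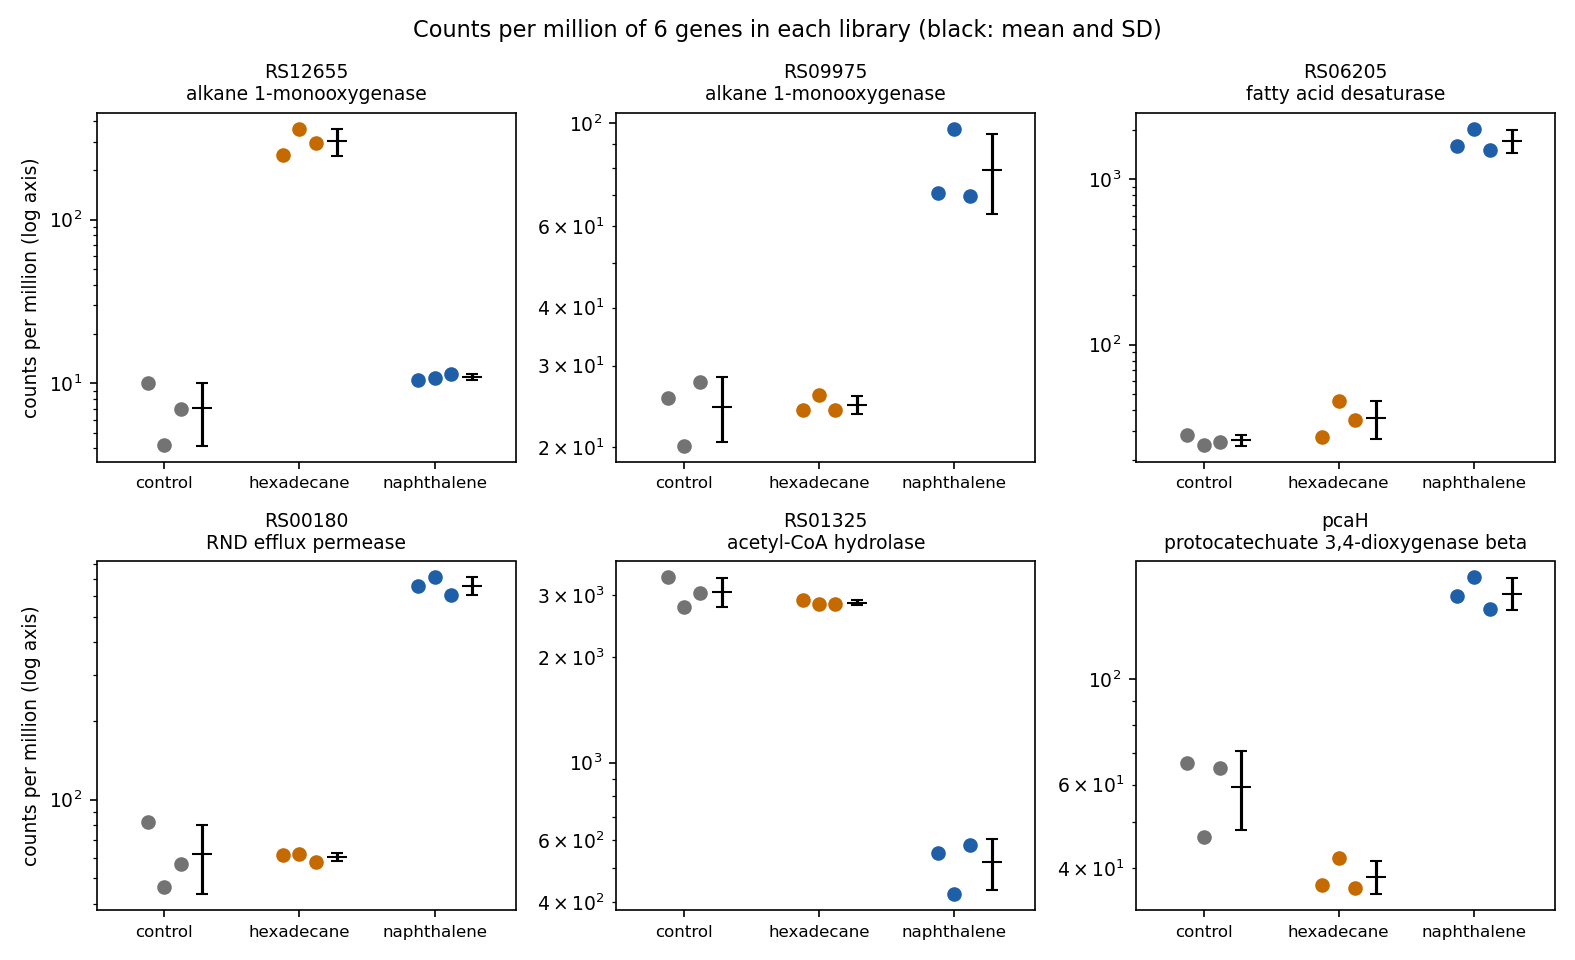
Expression of LRO55_RS12655, LRO55_RS09975, LRO55_RS06205, LRO55_RS00180, LRO55_RS01325 and pcaH in each library, as CPM on a logarithmic axis by group. Black marks show the mean and SD of 3 libraries, with LRO55_RS12655 high only with hexadecane and the other 5 panels changed with naphthalene.

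With hexadecane 27 genes were called, 22 higher and 5 lower, with 8 hypothetical proteins and 1 unannotated region among them, and 498 had an unadjusted p under 0.05 where 187 would be expected by chance. At least 2-fold were 5 genes: LRO55_RS12655, LRO55_RS11205, aroD, catA and the hypothetical protein LRO55_RS12160 (log2 fold change 1.47), the last chosen after its values were seen. The groups did not overlap for 17.9% of genes, where chance gives 10%. From the DESeq adjusted p-values that the authors deposited, 26 genes were called, 20 higher and 6 lower. Of these, 20 were also called here in the same direction. Of the 14 named genes, LRO55_RS12655 and LRO55_RS11205 kept their call in all 19 settings, which leave out the fits on FPKM. The other 12 lost it in 4 to 14 of these settings, with no change of direction. Without control library 3, 4 of the 14 lost it (highest adjusted p = 0.0651), without hexadecane library 1, 2 or 3, 11, 12 and 12 (0.192, 0.256 and 0.2), and without naphthalene library 1, 2 or 3, 10, 6 and 5 (0.133, 0.0865 and 0.0975). The count was 102, 125 and 43 without control library 1, 2 or 3, 5, 2 and 3 without hexadecane library 1, 2 or 3, and 8, 15 and 17 without naphthalene library 1, 2 or 3. It was 72 by DESeq2, 6 with upper-quartile factors, 2 with only the 6 libraries compared and 9 on FPKM. The count at 2-fold was 10, 2, 2 and 3 in these settings, and it was 43 and 9 without control library 2 or 3, 2, 1 and 2 without hexadecane library 1, 2 or 3, and 3 without naphthalene library 1. Scaling by total counts shifted the median of all genes by -0.118 and made 35% of 20 calls higher, against 81.5% with TMM.

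Naphthalene against control asked which transcripts responded to an aromatic hydrocarbon. LRO55_RS06205 is annotated as a fatty acid desaturase, the type of enzyme that places double bonds in fatty acids and so alters membrane fluidity. Its level went from 26.3 ± 1.89 to 1708 ± 273 CPM, a 64.8-fold rise (log2 fold change 6.02, SE 0.19, adjusted p = 4.79e-10). The gene lies at 1312426 to 1314666 on the plus strand. In the same stretch an efflux system of the RND type, which pumps toxic compounds out across both membranes, rose strongly. Its adaptor LRO55_RS06160 went from 5.47 ± 2.14 to 171 ± 33.4 CPM (31.0-fold) and its permease LRO55_RS06165 from 18.2 ± 3.54 to 343 ± 63.4 CPM (18.8-fold).

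Neighbours of this efflux system changed in opposite directions with naphthalene. The TolC family gene LRO55_RS06150, an outer membrane channel type, had 11, 1 and 4 counts in controls, 3, 0 and 2 with hexadecane, and 199, 247 and 140 with naphthalene. The oxidoreductase LRO55_RS06170 rose 14.8-fold and the MATE family transporter LRO55_RS06145 8.64-fold. On the other side of LRO55_RS06145, the LysE family translocator LRO55_RS06135 was 4.24-fold lower and the AraC family regulator LRO55_RS06140 4.03-fold lower. Another RND pair at 41236 to 45464 rose as well. Its adaptor LRO55_RS00175 went from 20.6 ± 0.939 to 273 ± 18.8 CPM (13.3-fold) and its permease LRO55_RS00180 from 61.7 ± 18.3 to 657 ± 51.4 CPM (10.6-fold). Adaptor and permease overlap by 4 bp in both pairs, so a few reads of each may belong to the other. The AdeB/AdeJ family permease LRO55_RS09260 rose by a log2 fold change of 0.86, its neighbour LRO55_RS09255 by 1.40 and amvA by 0.69, all chosen after their values were seen, whereas adeJ was at -0.08 (adjusted p = 0.664). Multidrug efflux as a list had 8 of 46 members higher and the other 38 not called, with 8 higher adjusted over the list alone too (camera adjusted p = 0.134). Its mean was 0.34, and its median of 0.00735 ran from -0.0752 to 0.00812 and so turned sign with the scaling.

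**Figure D2:**
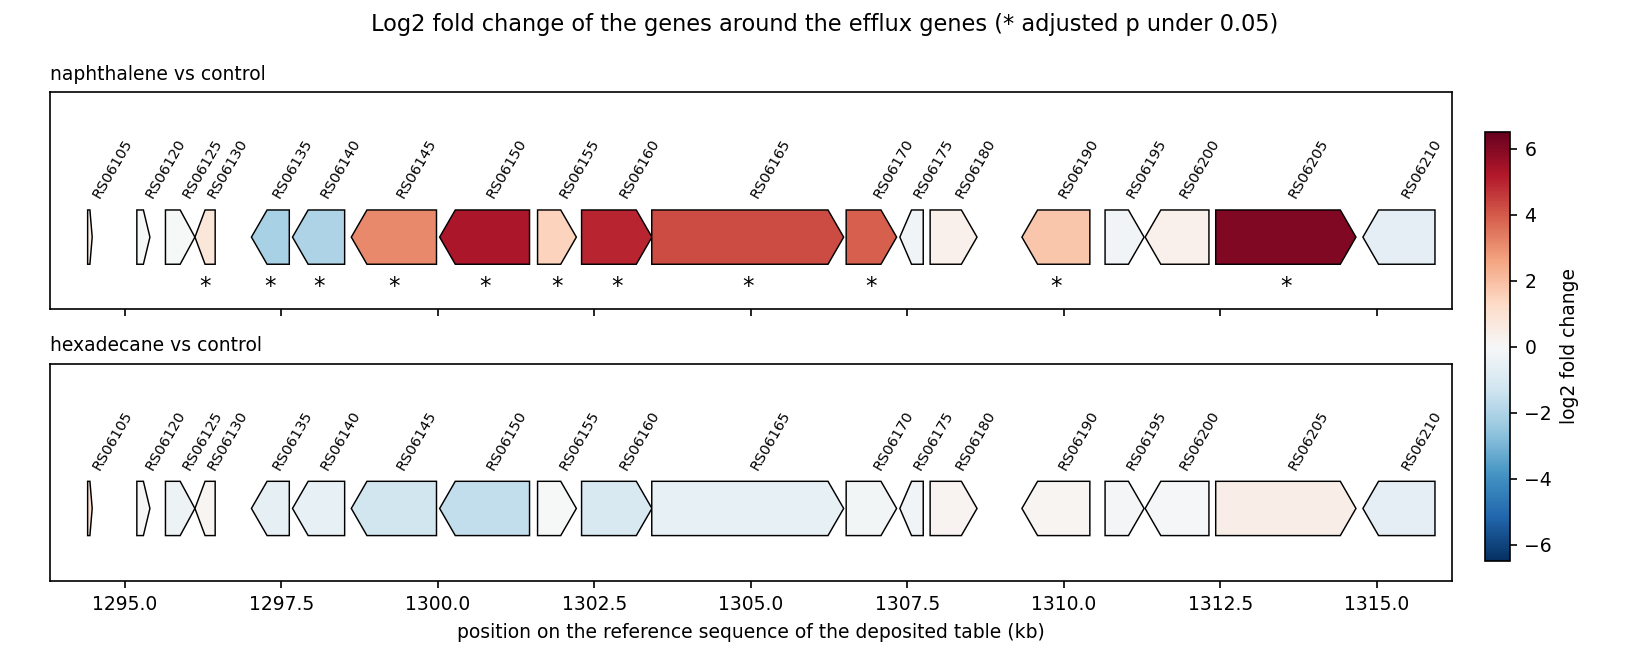
Genes from LRO55_RS06135 to LRO55_RS06205 and their neighbours, drawn by position (kb) and strand on the reference sequence and coloured by log2 fold change, with naphthalene against control above and hexadecane against control below. Stars mark an adjusted p under 0.05, and the efflux genes and the desaturase are starred only with naphthalene.

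The other named genes with naphthalene belonged to several annotated classes. The carotenoid oxygenase family gene LRO55_RS08590 rose 8.08-fold. LRO55_RS12945, the alpha subunit of an aromatic ring-hydroxylating dioxygenase, went from 85.5 ± 19.9 to 335 ± 31.0 CPM, a 3.92-fold rise (adjusted p = 6.35e-07). The metal-dependent hydrolase LRO55_RS12870 was 9.93-fold lower, from 37.1 ± 5.21 to 3.74 ± 1.03 CPM. LRO55_RS01325, an acetyl-CoA hydrolase/transferase, was 5.93-fold lower, from 3075 ± 296 to 519 ± 86.3 CPM, and the cation acetate symporter LRO55_RS00920 3.55-fold lower. The DJ-1/PfpI family gene LRO55_RS03475 was 3.41-fold lower, the dicarboxylate symporter LRO55_RS06420 3.03-fold, and the NTF2 family gene LRO55_RS08205 2.82-fold. All 20 named genes kept their call in every setting in which single genes were followed, 18 settings for benB and 19 for the others.

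Genes for breakdown of aromatic compounds moved in both directions with naphthalene. Expression of pcaH, a protocatechuate 3,4-dioxygenase subunit that opens the aromatic ring, went from 59.4 ± 11.2 to 151 ± 11.7 CPM (log2 fold change 1.35, adjusted p = 1.82e-05). The dioxygenase genes LRO55_RS08210 and LRO55_RS08215 fell by 1.38 and 1.35, and benA, of benzoate dioxygenase, fell by 1.36 (0.0037). The neighbouring benB was 3.25-fold lower (0.00292), and it overlaps benA by 4 bp, so a few reads may belong to either. The ferredoxin reductase LRO55_RS12610 was 2.91-fold lower. Neither catA (-0.32, adjusted p = 0.296) nor salA, annotated for salicylate hydroxylation (-0.51, 0.329), was called. In the list of 32, 10 rose and 5 fell over all genes, and 10 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.55). Of 11 phenylacetate degradation genes 0 were called by edgeR, 0 by DESeq2 and 0 by limma-voom, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.463), but 5 were higher without control library 3.

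Alkane and fatty acid genes responded to naphthalene in part. The alkane 1-monooxygenase LRO55_RS09975, at 2118733 to 2119956, went from 24.4 ± 3.85 to 79.1 ± 15.6 CPM, a 3.23-fold rise (adjusted p = 1.25e-05), whereas LRO55_RS12655 had a log2 fold change of 0.61 (0.165), and was called without control library 1 (0.96, 0.0397). The rubredoxin LRO55_RS13625, an electron carrier for such enzymes, fell by 0.56 (0.0177), a call lost without naphthalene library 1 (0.0511) or naphthalene library 3 (0.0777) and with only the 6 libraries compared (0.0587). The remaining member of the alkane list, ssuD, acts in sulfonate use and was not called. Fatty acid beta-oxidation had 12 of 45 members higher and 3 lower (camera adjusted p = 0.0804), and 9 higher and 5 lower with upper-quartile or total-count scaling. Among them LRO55_RS08395 rose by 1.82, LRO55_RS18045 by 0.87, LRO55_RS18040 by 0.97 and fadB by 0.51 (0.000802), and LRO55_RS08195 fell by 0.96. LRO55_RS18040 and LRO55_RS18045 lie beside LRO55_RS18060, a methylmalonate-semialdehyde dehydrogenase of valine breakdown that rose by 0.88. Alcohol and aldehyde dehydrogenases, which include LRO55_RS18060, had 6 of 25 higher and 3 lower (0.277), with LRO55_RS08625 at 1.29, putA at 0.84 and LRO55_RS05165 at 0.76. The wax ester synthase LRO55_RS03525 was at 0.09 (adjusted p = 0.62). Of 6 fatty acid synthesis genes 0 were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.847). Without control library 1, 1 of them was higher and 1 lower, and without control library 2, 1 was higher.

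Central carbon metabolism shifted gene by gene with naphthalene. Citrate synthase gltA fell by a log2 fold change of 1.20, from 2888 to 1255 CPM (adjusted p = 2.37e-06), sdhD fell by 0.51 and sdhC by 0.45, whereas the aconitate hydratase LRO55_RS15760 rose by 0.82. The TCA cycle list had 2 of 14 members higher and 4 lower (camera adjusted p = 0.463), and 1 higher with upper-quartile or total-count scaling. Malate synthase G (LRO55_RS10165), of the glyoxylate shunt, fell by 0.34 (0.00635), and isocitrate lyase LRO55_RS13560 was at -0.23 (0.103). The glyoxylate list has 4 tested members, of which leuA (0.26, adjusted p = 0.0506) and prpB (0.157) act in other pathways and were not called. By DESeq2 (0.0413), limma-voom (0.0484), RLE factors (0.0479), no filter (0.0457), the stricter filter (0.0486), leaving out the unannotated regions (0.029), control library 1 (0.00533) or naphthalene library 2 (0.048), leuA was called. Isocitrate lyase LRO55_RS13560 was called with total counts (0.046) and without control library 2 (0.0251). Amino acid catabolism had 2 of 17 higher and 6 lower (0.15), with hutU at -0.95, hutH at -0.66 and putP at 0.60. The call of sdhC was lost without naphthalene library 2 (0.0619) and that of hutH without naphthalene library 1 (0.0514).

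ATP synthase genes fell with naphthalene, as did some genes of NADH dehydrogenase I and of the ribosome. All 5 members of the ATP synthase list fell, among them atpB (-1.01, adjusted p = 1.59e-06), atpG (-1.04), atpA (-0.99) and atpD (-0.90), also adjusted over the list alone (camera adjusted p = 2.2e-06; adjusted p = 0.461 with an estimated correlation). By product name, a definition chosen after seeing the data, 9 of 9 subunits fell, with log2 fold changes from -1.23 to -0.86. NADH dehydrogenase I, the entry point of the respiratory chain, had 2 of 11 members lower and 5 adjusted over the list alone, with a median of -0.23 (0.00707; adjusted p = 0.808 with an estimated correlation). These were nuoC (-0.30, adjusted p = 0.0201) and nuoN (-0.27, 0.0483), and the list's call was lost without naphthalene library 2 (0.0681). The call of nuoC was lost without naphthalene library 2 (0.0723) or 3 (0.0586) and with only the 6 libraries compared (0.0792), and that of nuoN without control library 2 (0.0803) or 3 (0.124), hexadecane library 1, 2 or 3 (0.0844, 0.082 and 0.0923) or naphthalene library 1, 2 or 3 (0.132, 0.134 and 0.0927). That of nuoN was also lost by DESeq2 (0.0519), with RLE factors (0.0533), without a filter (0.0638), with only the 6 libraries compared (0.134) and without the unannotated regions (0.0689). With upper-quartile or total-count scaling 5 of the 11 were lower, and 1 with RLE factors. Ribosomal proteins had 9 of 59 lower, also adjusted over the list alone, with a median of -0.17 (0.00565; adjusted p = 0.827 with an estimated correlation). Examples were rplW (-0.54), rplD (-0.51), rpsJ (-0.49) and rplC (-0.47), and the list's call was lost without control library 2 (0.0787) or naphthalene library 2 (0.233). Terminal oxidases had 1 of 9 higher, the cytochrome d oxidase subunit LRO55_RS15005 (0.82, adjusted p = 5.3e-05; camera adjusted p = 0.585).

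Chaperones and proteases, which refold or remove damaged proteins, were higher with naphthalene. In this list 6 of 14 members rose over all genes and 7 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00558; adjusted p = 0.794 with an estimated correlation). Examples were clpA (0.73, adjusted p = 2e-05), dnaK (0.63), lon (0.63) and grpE (0.62), whereas groL was at -0.19 (0.347). Oxidative stress defence had 4 of 19 members higher and 4 lower (0.872), with the catalase genes katG at 0.65 (0.000417) and katE at -0.52 (0.0179), the latter call lost without naphthalene library 2 (0.0766) and with only the 6 libraries compared (0.0544). Other members were LRO55_RS10765 (0.51), trxC (0.44) and LRO55_RS04645 (-0.81).

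Envelope and osmotic stress genes rose in few cases with naphthalene. Envelope assembly had 3 of 15 higher (camera adjusted p = 0.121), carO (0.65), lolA and lptC, but 1 of 15 with upper-quartile or total-count scaling. Osmoprotection had 2 of 14 higher (0.412), betT (0.35) and proP (0.61), but 1 of 14 under those scalings. SOS response had 1 of 8 higher (0.55), uvrB (0.57, adjusted p = 0.00155). The call of carO was lost without control library 3 (0.0716), hexadecane library 1 or 2 (0.0532 and 0.0547) or naphthalene library 1, 2 or 3 (0.141, 0.0913 and 0.0939), that of betT without naphthalene library 1 (0.0687) and that of proP without naphthalene library 1 or 2 (0.091 and 0.0753). That of lolA was lost without control library 2 or 3 (0.0981 and 0.0736), hexadecane library 2 or 3 (0.0534 and 0.0636) or naphthalene library 1 or 3 (0.197 and 0.129). That of lptC was lost without hexadecane library 1, 2 or 3 (0.0603, 0.0674 and 0.0642) or naphthalene library 1, 2 or 3 (0.127, 0.0765 and 0.16). With upper-quartile factors and total counts the calls of betT (0.0527 and 0.0561), lolA (0.131 and 0.13) and lptC (0.059 and 0.073) were lost. With only the 6 libraries compared those of carO (0.0799), lolA (0.0875) and lptC (0.117) were lost, that of carO also without the unannotated regions (0.0519) and that of lptC also with the stricter filter (0.05).

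Surface and metal uptake lists changed in few members with naphthalene. Type VI secretion, a contact-dependent injection system, had 1 of 16 members higher, the VgrG protein LRO55_RS13165 (0.37), and 4 lower, among them tssF (-0.55; camera adjusted p = 0.0804), but 0 higher and 6 or 7 lower with upper-quartile factors or total counts. Type IV pili had 2 of 16 lower (0.134), pilB (-0.64) and LRO55_RS09180 (-0.76), the latter a type 1 fimbrial protein and so of another kind of pilus. Iron uptake had 2 of 38 higher and 1 lower (0.463), and with upper-quartile factors or total counts 0 higher and 1 or 2 lower. The copper receptor LRO55_RS17730 (lower, adjusted p = 0.00112) and znuD (0.60), a zinc receptor, carry other metals, and of the called members only LRO55_RS17345 (0.30) is annotated for iron. The single prophage gene, LRO55_RS09210, rose by 0.42 (0.0179). The call of pilB was lost without control library 3 (0.0787) or naphthalene library 2 or 3 (0.096 and 0.092), and that of LRO55_RS09180 without control library 3 (0.0611) or naphthalene library 1 or 2 (0.0598 and 0.106). That of znuD was lost without control library 2 (0.0524) or naphthalene library 1, 2 or 3 (0.0511, 0.0744 and 0.0538), and that of LRO55_RS09210 without naphthalene library 1 or 3 (0.0587 and 0.0537). That of LRO55_RS17345 was lost without control library 3 (0.129), hexadecane library 1, 2 or 3 (0.079, 0.0754 and 0.0798) or naphthalene library 1, 2 or 3 (0.25, 0.1 and 0.0895), and by DESeq2 (0.0513). With upper-quartile factors, total counts and only the 6 libraries compared the calls of LRO55_RS13165 (0.0547, 0.0539 and 0.0517), znuD (0.0595, 0.0503 and 0.061), LRO55_RS17345 (0.137, 0.17 and 0.139) and LRO55_RS09210 (0.0953, 0.0733 and 0.0623) were lost, and in the last of these settings that of pilB (0.061). In edgeR with TMM factors, DESeq2 and limma-voom 0 members were called in capsule (9 tested), iron-sulfur cluster assembly (8), sulfur acquisition (16) and outer membrane asymmetry (3), with 1, 3, 2 and 1 at an unadjusted p under 0.05. With upper-quartile factors or total counts 1 member of capsule and 2 of sulfur acquisition were lower, and 0 of the other lists were called. With 1 control library left out, at most 2 members of capsule and 1 of each other list were called. Camera adjusted p was 0.847, 0.847 and 0.302 for the lists of at least 5 among these. For iron-sulfur cluster assembly the median was -0.0889, the mean 0.034 and the test up, and for fatty acid synthesis the median was 0.0254, the mean -0.00355 and the test up.

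**Figure D3:**
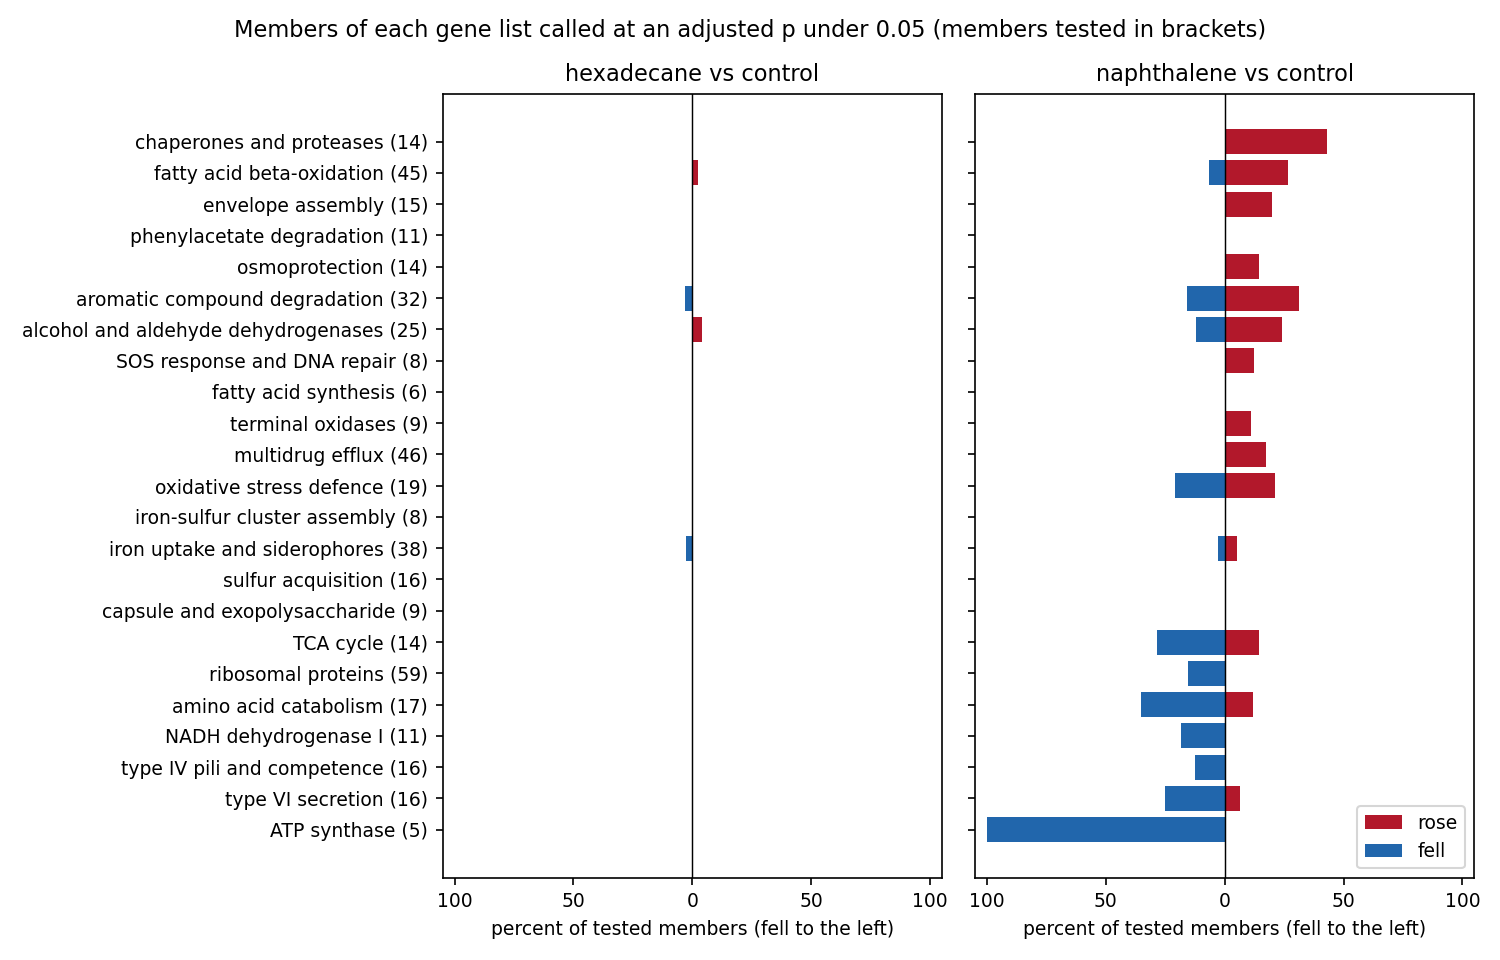
Percent of the tested members of each of 23 gene lists that rose or fell at an adjusted p under 0.05, for hexadecane and naphthalene against control. Bars for naphthalene are longest for ATP synthase, whereas few bars are visible for hexadecane.

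With naphthalene 608 genes were called, 364 higher and 244 lower, with 77 hypothetical proteins and 40 unannotated regions among them, and the median change of these was 1.58-fold. At least 2-fold were 159, 102 higher and 57 lower, and 129, 80 of them higher, without the unannotated regions. The groups did not overlap for 30.6% of genes, where chance gives 10%. From the DESeq adjusted p-values that the authors deposited, 381 genes were called, 245 higher and 136 lower. Of these, 376 were also called here in the same direction. The count was 387 without naphthalene library 1, 389 without naphthalene library 3 and 353 with only the 6 libraries compared. With total counts 42.1% of the calls were higher, against 59.9% with TMM, so the balance of rises and falls depended on the scaling.

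Hexadecane against naphthalene asked which transcripts differed between the compounds. LRO55_RS12655, the alkane 1-monooxygenase, was 27.5-fold higher with hexadecane. The hydrolase LRO55_RS12870 was 8.27-fold higher, the acetyl-CoA hydrolase/transferase LRO55_RS01325 5.52-fold, LRO55_RS03475 3.60-fold and the acetate symporter LRO55_RS00920 3.41-fold. The desaturase LRO55_RS06205 was 47.5-fold lower with hexadecane, the efflux adaptor LRO55_RS06160 63.6-fold, its permease LRO55_RS06165 27.2-fold and LRO55_RS06145 20.3-fold, beside LRO55_RS06150 with the counts given above. These 10 genes kept their call in all 19 settings, which leave out the fits on FPKM. The alkane 1-monooxygenase LRO55_RS09975 was lower with hexadecane (log2 fold change -1.68), as were pcaH (-1.98), catA (-0.76, adjusted p = 0.0222) and katG (-0.73), whereas gltA (1.09) and katE (0.75) were higher. The call of catA was lost without hexadecane library 1 or 2 (0.0793 and 0.0947) or naphthalene library 1 or 2 (0.0887 and 0.101).

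Gene lists differed between hexadecane and naphthalene in 9 cases by camera. ATP synthase was higher with hexadecane in 5 of 5 members (2.15e-06; adjusted p = 0.459 with an estimated correlation), NADH dehydrogenase I in 1 of 11 (0.0149; adjusted p = 0.55 with an estimated correlation), ribosomal proteins in 4 of 59 and 1 adjusted over the list alone (0.0297; adjusted p = 0.699 with an estimated correlation), and type IV pili in 1 of 16 (0.0437; adjusted p = 0.55 with an estimated correlation). Multidrug efflux was lower with hexadecane, with 9 of 46 members lower and 1 higher (0.000427; adjusted p = 0.55 with an estimated correlation), as were aromatic compound degradation with 11 of 32 lower and 2 higher (0.00531; adjusted p = 0.55 with an estimated correlation) and beta-oxidation with 13 of 45 lower and 4 higher (0.0149; adjusted p = 0.55 with an estimated correlation). Phenylacetate degradation was lower in 4 of 11 (0.0203; adjusted p = 0.577 with an estimated correlation) and iron uptake in 8 of 38 (0.0279; adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone, 10 were lower in efflux, 12 in aromatic degradation, 17 in beta-oxidation, 5 in phenylacetate degradation and 10 in iron uptake. With upper-quartile factors or total counts 0 members of NADH dehydrogenase I were called and 2 or 1 ribosomal proteins were higher, and in efflux 0 were higher. With membership by gene symbols only the call of efflux was lost (0.923). Without naphthalene library 2 the calls of NADH dehydrogenase I (0.0542), beta-oxidation (0.0644), phenylacetate degradation (0.0834), iron uptake (0.0834) and ribosomal proteins (0.575) were lost. Ribosomal proteins also lost theirs without hexadecane library 2 (0.0917) and type IV pili without naphthalene library 3 (0.0823). The list of type IV pili includes LRO55_RS09180, a type 1 fimbrial protein and so of another kind of pilus. Median, mean and test differed in sign for amino acid catabolism (0.00997, -0.097, up), iron-sulfur cluster assembly (0.0851, -0.00163, up), SOS response (-0.0258, 0.000502, up) and sulfur acquisition (-0.000923, -0.0249, up).

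Between hexadecane and naphthalene 497 genes were called, 220 higher and 277 lower with hexadecane, with 53 hypothetical proteins and 38 unannotated regions among them. At least 2-fold were 142, 43 higher and 99 lower, and the groups did not overlap for 39.9% of genes, where chance gives 10%. The count was 878 without control library 1, 294, 316 and 313 without hexadecane library 1, 2 or 3, and 1024 with only the 6 libraries compared.

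The number of shared calls was limited by the 27 genes called with hexadecane. Called in the same direction against control were 11 genes, 10 higher and 1 lower, among them modA (log2 fold change 0.70 with hexadecane and 1.35 with naphthalene), the flavodoxin family gene LRO55_RS03830 (0.48 and 0.36), LRO55_RS18060 (0.43 and 0.88) and LRO55_RS11855 (-0.64 and -1.08). The OmpA family gene LRO55_RS14265 (0.41 and 0.31) and LRO55_RS12370 (0.88 and 0.54) were also shared, both chosen after their values were seen. Opposite directions were called for aroD (-1.10 with hexadecane and 0.62 with naphthalene). They were also called for LRO55_RS02315 and LRO55_RS11210, annotated as hypothetical proteins and chosen after their values were seen. LRO55_RS11210 spans only positions 2367292 to 2367315, so its counts may come from reads that extend beyond it. Independent lists would share 2.14 higher and 0.326 lower. Simulated unchanged groups against the same controls shared a mean of 0.06 and at most 1 in 50 draws. Few genes are called where none is changed, so this simulation cannot show how many genes lists with real changes would share through the controls. Log2 fold changes of the compounds correlated across genes at 0.36, against 0.496 in the simulation, with a covariance of 0.0708 against 0.0333. The simulation gave all groups the same spread per gene, although controls correlated less within their group than treated libraries. Its covariance may therefore be too low, and no conclusion is drawn from the difference. The controls are common to both comparisons, and 3 libraries cannot be divided evenly between them. A division of 1 against 2 control libraries was not tried. The shared count was 60, 65 and 25 without control library 1, 2 or 3, 2, 0 and 1 without hexadecane library 1, 2 or 3, 4, 7 and 7 without naphthalene library 1, 2 or 3, 28 by DESeq2, 3 with upper-quartile factors and 0 with only the 6 libraries compared.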

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

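Leaving out the unannotated regions and defining ATP synthase by product name were chosen after seeing the data; the other alternatives were planned. No call of a named gene or list turned its direction under the alternatives tried. Where a count moved between settings, the cause was not tested. The fit of all 9 libraries pools the spread over groups, yet controls correlated less within their group (0.969 to 0.982) than treated libraries (0.987 to 0.99). With only the 6 libraries compared, calls against control fell from 27 to 2 and from 608 to 353, and those between the compounds rose from 497 to 1024. The p-values against control may therefore be too small.

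For hexadecane against control, 27 genes became 6 with upper-quartile factors, 72 by DESeq2, 2 with only the 6 libraries compared, 9 with the replicate number as a block, 9 and 9 on FPKM with pseudocounts of 1 and 0.1, and 2 to 125 with 1 library left out. Of the 27, DESeq2 shared 27, total counts 12, the block 8, upper-quartile factors 6 and the fit of 6 libraries 2. At 2-fold, 5 became 2, 10, 2, 3, 3 and 3 in the same order of settings and 1 to 43 with 1 library left out (43 and 9 without control library 2 or 3, 2, 1 and 2 without hexadecane library 1, 2 or 3, 3 without naphthalene library 1). For naphthalene against control, 608 became 353 with only the 6 libraries compared and 387 to 851 with 1 left out (387 and 389 without naphthalene library 1 or 3), with 518 in the block. At 2-fold it stayed within 135 to 213 with 1 left out. For hexadecane against naphthalene, 497 became 1024 with only the 6 libraries compared and 294 to 878 with 1 left out, with 440 in the block. The 11 shared genes became 3 with upper-quartile factors, 28 by DESeq2, 0 with only the 6 libraries compared, 4 in the block and 0 to 65 with 1 left out.

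With an estimated correlation 0 lists were called in each of the 3 contrasts, against 7, 4 and 9 with the preset one. By fry 0 lists were called for hexadecane against control, 6 for naphthalene against control and 6 between the compounds. With naphthalene these included multidrug efflux (fry adjusted p = 0.0243), sulfur acquisition (0.0422) and alcohol and aldehyde dehydrogenases (0.0439), which camera did not call. Ribosomal proteins were called by camera but not by fry (0.142). Membership by symbols only could be tested for 6 of the 9 lists called between the compounds, of which 5 kept their call. With 1 library left out the counts of lists were 5 to 8, 2 to 7 and 5 to 11; the lowest for naphthalene against control (2) and between the compounds (5) came without naphthalene library 2, and 7 came without control library 1 or 3. Without the unannotated regions 24 and 604 genes were called for hexadecane and naphthalene against control. At 2-fold the count for naphthalene against control then fell from 159 to 129, and that between the compounds from 142 to 122.

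Of 304 values of 16 genes called with hexadecane, 183 kept their call and 121 lost it, against 1395 of 1500 kept for 79 genes with naphthalene and 1143 of 1235 for 65 genes between the compounds. Library numbers gave no pairing: 0 of 9 pairs correlated above 0.1 (-0.196 to 0.084) and 1 of 9 libraries correlated best with its own number. Upper-quartile and total-count scaling shifted the median of all genes by -0.0949 and -0.118 with hexadecane and by -0.0804 and -0.0826 with naphthalene. Depth limits genes under 0.957 CPM, the level of 3 counts in the smallest library.

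Each contrast allows 10 splits of its 6 libraries, too few for a share under 0.05. The other splits mix libraries of both real groups, so any real change adds to the spread within their groups. Low gene counts in them therefore do not show how many genes would be called where nothing changed. For hexadecane against control 1 of 10 splits, the real one, gave as many genes (27, highest other 2) and 1 as many at 2-fold (5, highest other 2), and 2 gave as many lists (7, highest other 8). For naphthalene against control these were 1 (608, highest other 0), 1 (159, highest other 0) and 6 for lists (4, highest other 7). Between the compounds they were 1 (497, highest other 0), 1 (142, highest other 0) and 1 for lists (9, highest other 6).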

Other observations

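The tests of strand marking, of gene length, of genomic DNA, of a label swap and of control library 1 alone in this part, and the count of neighbouring genes, were chosen after the result was seen.

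Genes that lie side by side changed together with naphthalene. Runs of at least 4 neighbouring genes on the same strand called in the same direction numbered 5 higher and 6 lower, with 74 genes in them, against a mean of 0.095 and at most 2 in 1000 shuffles of the calls along the sequence. The longest higher run held 13 genes, LRO55_RS08060 to LRO55_RS08120, with pca genes of protocatechuate breakdown, aroD and quinate/shikimate dehydrogenase (median log2 fold change 1.35). Another held 7 genes, LRO55_RS18030 to LRO55_RS18060, with dehydrogenases of valine breakdown (0.88), and a run of 7 from LRO55_RS05175 to sohB held phosphate transport genes (0.57). LRO55_RS06155 to LRO55_RS06170 held the efflux genes (4.06) and LRO55_RS09550 to LRO55_RS09565 a CoA transferase (1.07).

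Lower runs with naphthalene held 9 genes from LRO55_RS08190 to LRO55_RS08230, with a ring-hydroxylating dioxygenase, an amidase and an acyl-CoA dehydrogenase (median log2 fold change -1.37), and 9 genes of ATP synthase, LRO55_RS17790 to LRO55_RS17830 (-1.01). A run from rpsJ to rplV held 7 ribosomal protein genes (-0.47) and a run from LRO55_RS01820 to astB 5 genes that include arginine breakdown (-0.41). Runs of 5 and 4 genes lay from LRO55_RS11845 to LRO55_RS11865 (-0.96) and from LRO55_RS17725 to LRO55_RS17740 (-0.88). The chosen names follow the runs and so were chosen after their values were seen.

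Unannotated regions moved with the annotated gene on the opposite strand: 426 regions lie opposite such a gene, at a median of 2.77% of its read density (0.963 to 12.7% for the central 90% of regions). Log2 fold changes of region and gene with naphthalene correlated across 327 pairs at 0.672, above the range of shuffled pairings (upper bound 0.107), and the correlation was 0.351 with hexadecane. Of the 40 regions called with naphthalene, 31 had their gene called in the same direction and 0 in the opposite one, which is consistent with reads whose strand was not marked. The ratio of region to gene differed with naphthalene in 0% of 327 pairs by limma, but 41 pairs had an unadjusted p under 0.05, a condition added after the 0% was seen, so whether such reads are the only source is left open. Transcripts of their own in some regions may add to the counts.

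Control library 1 stood apart from the other controls, with ssrA at 2.48% of its counts against 5.08 to 8.91% in the other 8 libraries. With its trend on gene length removed its lowest correlation with the other controls was 0.971, still under the 0.982 between these, which argues against gene length as the whole cause. Genomic DNA would add little to strongly expressed genes, yet among the most expressed 20% of annotated genes the SD of its log2 differences from another control was at least 1.85 times (95% range 1.56 to 2.21) that between the other controls, which argues against DNA there, whereas DNA is left open for weakly expressed genes (median 0.203 in the lowest 20%), since the -0.452 over unannotated regions may reflect the fewest unmarked reads (1.96% of the opposite gene's density against 3.45 and 2.35%). A test on mean correlations (0.972 with the other controls, 0.97 with hexadecane, 0.958 with naphthalene) left a label swap undecided, so a position between groups over genes called at 2-fold without this library was tried next; the library lay at 0.0849 (upper quartile 0.288) towards naphthalene over 148 genes and 0.0195 towards hexadecane over 7, where a swapped library would lie near 1. Differences in RNA handling, sampling time or culture remain open and were not tested.

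Aromatic compound degradation genes were lower with hexadecane, with 26 of 32 members below 0 and a median log2 fold change of -0.433. Weakly expressed genes were generally lower than in controls (median -0.29 in the lowest 20% by expression). The list's median lay at percentile 0 of 10000 random lists matched on expression (2.5th percentile -0.175). Random lists ignore that members vary together (estimated correlation 0.183), so their range is too narrow. Whether the list departs from the trend of weakly expressed genes is therefore left open. Without control library 1 the median was -0.359, 83% of its value, with 24 members below 0, which argues against that library as the only cause. A response of these genes to hexadecane may explain the pattern, as a hypothesis found and tested on the same data. Members that vary together remain open as another explanation, since the list was not called with an estimated correlation (adjusted p = 0.528), as does an untested difference in sampling time, which the labels do not give for the controls.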
